A study of Oryza sativa with 4 samples.

How the data were processed

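Small RNA was sequenced from shoots of rice (Oryza sativa ssp. japonica, cultivar Nipponbare) in 4 libraries, 1 per group. Plants germinated for 4 d and then grew for 12 d in nutrient solution. Shoots were taken from NT plants and from plants silenced for ASR5 by RNA interference (ASR5_RNAi), each untreated (control) or exposed for 8 h to 450 µM aluminium chloride at pH 4.5 (Al). The labels of the controls give no pH or treatment time, so aluminium cannot be told apart from acid pH or a change of solution. Al below stands for the whole treatment. The labels of the NT libraries do not name their genotype, which was read from the protocol and from the absence of the ASR5 RNAi label. Per the labels, RNA of 20 to 30 nt was cut from a gel, ligated to adapters, amplified and sequenced on an Illumina HiSeq, and low-quality reads and adapter sequence were removed.

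The deposited values are counts: the number of reads of each distinct sequence, without scaling. Tested on the values, the sequences were 18 to 24 nt long and between 0.359% and 0.381% of reads held an undetermined base. The length filter, an aligner and a genome build were not given in the sources used here, and no alignment was needed for the counts. Library totals outside 18 to 24 nt were not given, so the depth of each library is its total in that range.

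Reads were matched exactly, over their whole length, to 83 mature rice miRNA sequences of 37 families and to 7 sequences of other organisms that served as controls for foreign reads. This list, its groups by target (HD-ZIP III regulators, SPL regulators of growth phase, auxin and development, copper proteins, growth-regulating factors, and monocot or rice miRNAs, besides smaller groups) and the rules for named miRNAs were fixed before the data were examined. The list was recalled from memory and was not checked against a miRNA database or a genome, so a name stands for the listed sequence. Sequences with identical mature forms in several loci were counted once, and reads shared between loci cannot be assigned to 1 of them.

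Levels (RPM) are reads per 1000000 reads of 18 to 24 nt. In all, 4 comparisons were made: Al against control in NT and in ASR5_RNAi, and ASR5_RNAi against NT in control and in Al plants. A listed miRNA was measured in a comparison with at least 50 reads over its pair of libraries. It was counted as higher or lower when its ratio was at least 2-fold and the exact conditional binomial 95% interval of the ratio excluded 1. With 1 library per group these intervals compare libraries, not conditions, and no test of a condition was run. An additive model of genotype and Al, which would leave 1 residual degree of freedom, was not fitted. Levels have exact Poisson intervals and shares have Clopper-Pearson intervals. All intervals and floors cover counting error only, since amplified reads are not independent molecules. They do not cover reads carried over between libraries, which matter most for levels of few reads. A count of 0 was replaced by a floor of 3 reads, and such a ratio is given as a value at the floor. The floor was 0.408 RPM in NT control, 0.376 in NT Al, 0.852 in ASR5_RNAi control and 0.469 in ASR5_RNAi Al.

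For each comparison, the miRNAs named were up to 10 with the largest increase and up to 10 with the largest decrease among those counted. The most abundant listed sequence of each of 20 families was named as well, whatever its change. An unlisted form can be more abundant, as the 22 nt form of miR167 was. Group medians were set against 10000 random lists of the same size, drawn for each member from the 10 nearest miRNAs in abundance. Groups with fewer than 3 measured members have no percentile. The random lists draw separate miRNAs, while groups can hold related sequences of the same family. The HD-ZIP III group holds miR166 alone and the growth-regulating factor group miR396 alone. A percentile therefore does not give how unusual such a group median is. Other sequences of 20 to 24 nt were counted when they reached 100 RPM in a library and differed at least 4-fold in the same direction in both Al comparisons or in both comparisons of genotypes.

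The planned match to the ASR5 transcript was not possible because the reference files held no sequences. In its place, after the data were seen, sequences of at most 22 nt that were at least 50-fold higher in the ASR5_RNAi libraries were joined by overlaps of 17 nt. The joined sequence was searched for a recalled protein motif of the ASR family and for a recalled bacterial marker protein that serves as a spacer in hairpin vectors. Reads of 20 to 24 nt matching its ASR part exactly on either strand were then counted in every library. Fragments of tRNA and 5.8S rRNA were counted as reads that start with one of 26 recalled 18 nt prefixes, a list also written after the data were seen.

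Alternatives were scaling to the sum of listed miRNA reads, TMM scaling, DESeq2 median-of-ratios scaling, minimums of 10, 1 and 500 reads, reads sharing the first 18 nt of a miRNA (isomiRs), summed families and, added after the data were seen, scaling without reads of 18 and 19 nt and without the listed fragments. Analyses that need a genome sequence were left out: matches to the ASR5 transcript, classes of reads by reference, scaling or filtering by genome match, and unique matches. Calling was tested on simulated data of 1000 features: in each of the 4 comparisons 100% of 4-fold changes and of unchanged features were called right, and between 43.8% and 52.6% of 2-fold changes. Of 1.5-fold changes, which lie under the threshold, between 0% and 4.65% were called. The simulated counts held counting error only, with no variation between plants or preparations and no shift of composition. They therefore do not give the rate of false calls in the real libraries. Joining rebuilt 599 of 600 nt of a simulated sequence. The tools were R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.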

Results

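Small RNA reads of 18 to 24 nt were collected from rice shoots in 4 libraries, 1 for each combination of genotype (NT or ASR5_RNAi) and treatment (control or Al), so there were no replicates. The libraries held 7350415 reads in NT control, 7983555 in NT Al, 3522239 in ASR5_RNAi control and 6391749 in ASR5_RNAi Al. They held 2797131, 3089758, 1003856 and 2295629 distinct sequences in the same order. Of the 83 listed rice miRNA sequences 70 were read in at least 1 library, and listed miRNAs made up 17.03% of reads in NT control, 13.9% in NT Al, 3.06% in ASR5_RNAi control and 7.81% in ASR5_RNAi Al.

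The first question was whether small RNAs from the silencing construct were present in the ASR5_RNAi libraries. ASR proteins (abscisic acid, stress and ripening) include ASR5, which acts like a transcription factor and is tied to aluminium tolerance in rice. Sequences far more abundant in the ASR5_RNAi libraries joined into stretches of 951 and 617 nt. The stretch of 951 nt held a 417 nt coding part of 139 codons with 25 residues in a row of the ASR family motif, next to vector sequence. Small RNAs of 20 to 24 nt from this ASR part reached 28489 RPM (95% interval 28314 to 28666) in ASR5_RNAi control and 53320 RPM (53141 to 53499) in ASR5_RNAi Al. In NT they were at 12.4 RPM (9.97 to 15.2) in control and 13.3 RPM (10.9 to 16.1) in Al. Reads from the linker and vector part of the joined sequence were also found in NT, at 7.21 RPM in control and 4.89 RPM in Al. The NT levels may therefore include reads carried over from other libraries, which was not tested. For the ASR part the ratio of ASR5_RNAi to NT was 2301 (1874 to 2858) in control and 4016 (3320 to 4905) in Al plants. Within ASR5_RNAi the level was 1.87-fold higher with Al in RPM (log2 0.90), but the log2 ratio was -0.45, -0.46 and -0.37 with scaling to listed miRNA reads, TMM and DESeq2. Both strands were read: antisense reads were at 9812 and 17667 RPM in ASR5_RNAi control and Al, against 2.72 and 2.51 RPM in NT. Reads of 21 nt, the usual length of hairpin siRNAs, made up 68.4% and 75.2% of the reads from this part in ASR5_RNAi control and Al. The most abundant of them, GTAGACTCCTACGGCGAGGGC, lay on the sense strand at positions 67 to 87 from the start of the ASR part, with 1503 and 3120 RPM in ASR5_RNAi. The joined sequence was built from reads at least 50-fold higher in ASR5_RNAi, so a high ratio was partly set by that choice. Its identity as ASR5 rather than another ASR gene was not checked against a reference.

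**Figure D1:**
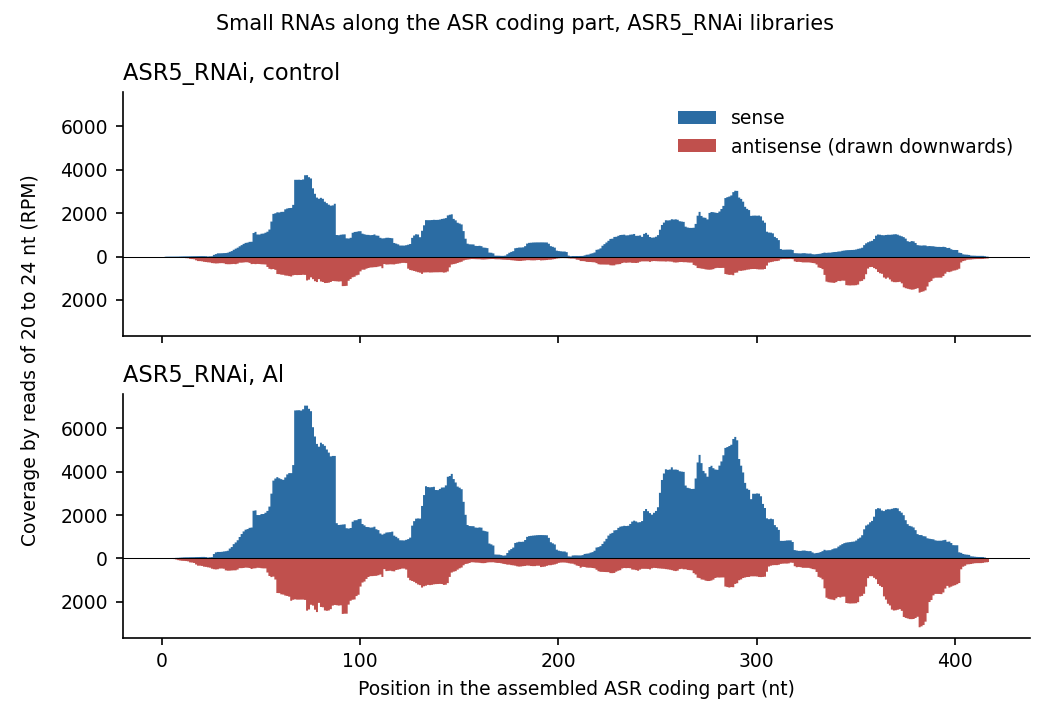
Coverage in RPM of each position of the 417 nt ASR part by small RNAs of 20 to 24 nt, with the sense strand drawn upwards and the antisense strand downwards, in the ASR5_RNAi control and ASR5_RNAi Al libraries. In ASR5_RNAi Al coverage peaked at 7068 RPM on the sense strand (position 72) and at 3154 RPM on the antisense strand (position 382).

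The libraries differed in composition. Reads of 24 nt, the length of siRNAs that direct DNA methylation, made up 48.4% (48.4 to 48.4) of reads in NT control and 47.5% (47.4 to 47.5) in NT Al, against 24.2% (24.2 to 24.3) in ASR5_RNAi control and 33.7% (33.7 to 33.8) in ASR5_RNAi Al. Reads of 21 nt, the length of most miRNAs, made up 23.9%, 21.3%, 14.2% and 22.9% in the same order, and reads of 19 nt 2.97%, 3.71%, 22.5% and 8.54%. Fragments from the start of 5 cytosolic tRNAs made up 0.535%, 0.907%, 12.1% and 2.59% of reads. A fragment of an arginine tRNA, the commonest in both ASR5_RNAi libraries, was at 1608 RPM in NT control and 89419 RPM in ASR5_RNAi control, a 55.6-fold difference, and was 6.90-fold higher in ASR5_RNAi than in NT with Al.

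**Figure D2:**
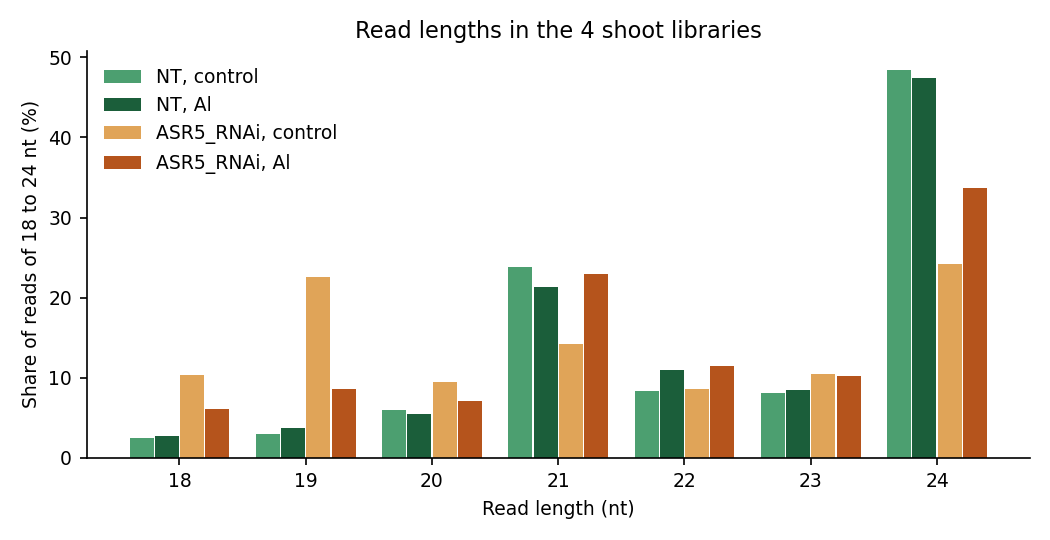
Percent of reads at each length from 18 to 24 nt in the 4 libraries. Reads of 24 nt were the largest class in each library, and reads of 19 nt made up 22.5% of ASR5_RNAi control.

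The next question was how Al changed miRNAs in NT shoots. Of 43 measured miRNAs, 10 were higher with Al, 4 were lower and 29 were neither. miR394, which targets an F-box gene of meristem and leaf development, was 9.46-fold higher (log2 3.24, interval 2.84 to 3.67), from 7.35 to 69.5 RPM. The miR444 family, which targets MADS-box genes, was higher in both measured members: miR444b.1 was 5.91-fold higher (log2 2.56, 2.32 to 2.81) and miR444a-3p.2 was 3.59-fold higher (log2 1.84, 1.63 to 2.06). miR156a, which holds back SPL genes of the change from juvenile to adult growth, was 6.83-fold lower (log2 -2.77, -2.79 to -2.75), from 17585 to 2575 RPM. Members of miR166, which targets HD-ZIP III genes of leaf polarity and vasculature, were also lower.

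By group, 3 of 5 HD-ZIP III regulators were lower with Al in NT, namely miR166k-3p (log2 -1.44), miR166e-3p (-1.34) and miR166g-3p (-1.03), and their median of -1.03 was at percentile 0 of random lists. miR166g-3p was not counted with TMM (-0.95) or scaling to listed miRNA reads (-0.73), and the group median was -0.76 with isomiRs. The abundant miR166a-3p was at -0.31, not counted. All 5 are related members of the miR166 family, so the percentile, which takes them as separate miRNAs, does not give how unusual their median was. Of 9 auxin miRNAs 2 were higher, namely miR164d (1.12), whose family targets NAC genes, and miR393a (1.10, 0.87 to 1.33), which targets auxin receptors. With DESeq2 scaling neither was counted (0.97 and 0.95), and with isomiRs miR393a was not (0.87). The group median was 0.51, at percentile 86.57. Of the 5 miRNAs against copper proteins 1 was higher, the laccase regulator miR397a (1.38, 0.69 to 2.12), while miR398b (0.61), miR408-3p (-0.23) and miR528 (-0.30) were not counted. That group's median was -0.23, at percentile 20.11, and 0.068 with scaling to listed miRNA reads. Of 3 SPL regulators miR156a alone was lower, with a group median of -0.73 at percentile 5.59 that was -1.58 with isomiRs. Of 3 miRNAs against growth-regulating factors miR396a-5p was higher (1.61, 0.85 to 2.43), though not with isomiRs (0.061), and the abundant miR396e-5p was at 0.091. That group's median was 0.091, at percentile 66.41, and -0.062 with DESeq2 scaling. Of 6 monocot or rice miRNAs 2 were higher, miR1425-5p (1.84, 1.64 to 2.05) and miR1432-5p (1.21), although miR1432-5p was at -0.60 when isomiRs were summed. Their median was 0.23, at percentile 51.55, and -0.45 with isomiRs. The NF-YA regulator miR169b was higher at 1.07, but not counted with DESeq2 scaling (0.91). The other named miRNAs were miR159a.1 (-0.48), miR160f (-0.25), miR164a (0.74), miR167a (0.20), miR168a (0.14), miR172a (0.65), miR390 (-0.19), miR399d (-0.44) and miR827 (0.45), none counted, while miR319a and miR395b had too few reads.

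The median log2 ratio of all measured miRNAs with Al in NT was 0.091, and relative to it 9 were at least 2-fold higher and 4 at least 2-fold lower. With scaling to listed miRNA reads the median moved by 0.30 and the counts were 13 higher and 3 lower, and with DESeq2 scaling it moved by -0.15 and the counts were 7 and 5.

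The same comparison in ASR5_RNAi shoots asked whether the response to Al took another form when ASR5 was silenced. Of 28 measured miRNAs, 24 were higher with Al, none was lower and 4 were neither, and the median log2 ratio was 1.45. The ratios had an interquartile range of 0.60 around that common shift, against 1.27 with Al in NT. Each other scaling moves all ratios by 1 factor: with listed miRNA reads, TMM or DESeq2 the median moved by -1.35, -1.37 and -1.27, and 2 miRNAs were higher under each. Relative to the median, 2 were at least 2-fold higher and 1 at least 2-fold lower. The higher ones were miR394 (log2 2.90, 1.71 to 4.38, or 1.45 above the median) and miR164e (2.59, 2.37 to 2.82, or 1.14 above the median). The lower one was miR1862d, at 0.31, or -1.14 from the median. Over the same pair of libraries, reads of 19 nt went from 22.5% to 8.54% and cytosolic tRNA fragments from 12.1% to 2.59% of reads.

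By group, 8 of 8 auxin miRNAs were higher with Al in ASR5_RNAi, with a median of 1.68 (percentile 98.59, and 0.32 with TMM scaling) that included miR164a (1.82), miR167a (1.81), miR167d (1.88), miR164d (1.55) and miR390 (1.44). With each of the 3 other scalings 1 of the 8 was higher. Of 4 HD-ZIP III regulators, all of the miR166 family, 2 were higher, none with the other scalings. Their median of 1.01, which was -0.36 with TMM scaling, was at percentile 0, with the same limit for related members. All 4 lay below the median of all miRNAs, with miR166a-3p at 0.97 (-0.38, -0.40 and -0.30 with scaling to listed miRNA reads, TMM and DESeq2). Of 4 monocot or rice miRNAs 3 were higher, none with the other scalings, including miR1425-5p (1.88), with a median of 1.38 at percentile 32. Both measured SPL regulators were higher, namely miR535-5p (1.96) and miR156a (1.46). The other named miRNAs were higher too: miR169b (1.93), miR444b.1 (1.53), miR159a.1 (1.52), miR168a (1.46) and miR396e-5p (1.11), the last with a negative ratio under TMM (-0.26), DESeq2 (-0.16) and scaling to listed miRNA reads (-0.25). No copper miRNA had enough reads in this pair, nor did miR160f, miR172a, miR319a, miR393a, miR395b, miR399d and miR827.

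**Figure D3:**
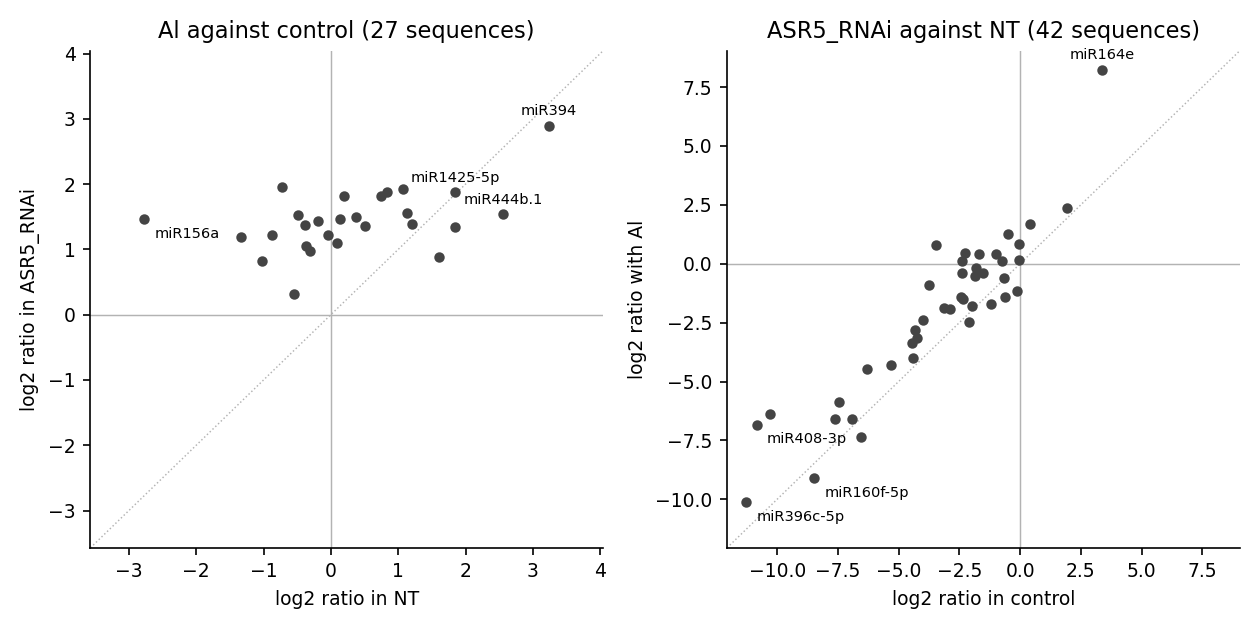
Log2 ratios of single miRNAs in pairs of comparisons that share no library, Al against control in NT and in ASR5_RNAi on the left and ASR5_RNAi against NT in control and in Al on the right. miR394 was higher with Al in both genotypes (log2 3.24 and 2.90), and miR164e was higher in ASR5_RNAi under both conditions (3.36 and 8.24). The miR164e ratios rest on 36 reads in NT control and 8 in NT Al.

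Across the 27 miRNAs measured in both genotypes, Al ratios had a Pearson r of 0.48 and a Spearman rho of 0.42. These are correlations across miRNAs, which are not independent replicates. Of 8 miRNAs higher in NT and 23 higher in ASR5_RNAi, 7 were shared, where 6.81 would be shared by chance. The difference of the log2 Al ratios, ASR5_RNAi minus NT, was at least 2-fold positive in 17 of 27 miRNAs and negative in 1, miR444b.1 (-1.03), with a median of 1.13. It was largest for miR156a (4.23, interval 4.19 to 4.28), followed by miR535-5p (2.69), miR166e-3p (2.52, 1.62 to 3.43), miR160a (2.11) and miR159a.1 (2.01). The differences carried the common shift, and with TMM scaling 3 were positive and 7 negative. With scaling to listed miRNA reads the counts were 2 and 7, and with DESeq2 scaling 3 and 5.

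The comparison of ASR5_RNAi with NT under control conditions asked what silencing of ASR5 changed without Al. Of 42 measured miRNAs, 2 were higher in ASR5_RNAi and 31 were lower, with a median log2 ratio of -2.39. The higher ones were miR164e (3.36, 2.84 to 3.92) and miR164d (1.94, 1.27 to 2.63), which target NAC genes. The largest decreases were in miR396c-5p, against growth-regulating factors, at 2454-fold lower (log2 -11.26, -12.88 to -10.04), miR408-3p (-10.84, -16.15 to -8.36, from 1 read in ASR5_RNAi) and miR166k-3p (-10.30, -13.35 to -8.45). miR528-5p and miR408-5p had 0 reads in ASR5_RNAi control. With these counts at the floor they were 197-fold and 92.3-fold lower, values that are not lower limits. The upper ends of their log2 intervals were -7.32 and -6.23. The abundant miR396e-5p was 39.8-fold lower (log2 -5.32), from 49136 to 1234 RPM. These decreases are in RPM and become smaller with the other scalings. Scaling to listed miRNA reads, TMM and DESeq2 moves log2 ratios of this comparison by 2.48, 3.17 and 2.0.

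By group, 4 of 4 copper miRNAs were lower in ASR5_RNAi control, with a median of -7.28 (-4.10 with TMM scaling) at percentile 0.49 when 0 counts stood at the floor. They included miR398b (-6.93), which targets copper/zinc superoxide dismutase. The phosphate regulators miR399d (-7.46) and miR827 (-4.25) were lower as well. All 3 SPL regulators were lower, among them miR156a (-3.46), with a median of -3.46 at percentile 34.19 that was -0.28 with TMM scaling. With scaling to listed miRNA reads, TMM and DESeq2 0, 0 and 2 of the 3 were lower. Of 10 auxin miRNAs 2 were higher and 7 lower, among these miR160f (-8.49), miR393a (-4.42), miR164a (-4.43) and miR167a (-4.01), and their median of -2.13, at percentile 68.87, was 1.04 with TMM scaling, where 5 were higher and 3 lower. miR390 (-1.81) was lower too, but was at 0.67, 1.36 and 0.19 with scaling to listed miRNA reads, TMM and DESeq2. Of 5 HD-ZIP III regulators 3 were lower, including miR166g-3p (-6.31), while miR166a-3p was at 0.42 and was higher at 2.90, 3.59 and 2.42 with scaling to listed miRNA reads, TMM and DESeq2. Their median of -2.40, at percentile 49.62, was 0.77 with TMM scaling, where 2 were higher and 2 lower. Of 6 monocot or rice miRNAs 2 were lower, with a median of -0.63 at percentile 99.25 that was 2.54 with TMM scaling. With scaling to listed miRNA reads, TMM and DESeq2 4, 5 and 4 of them were higher and none was lower. miR172a (-4.31) was lower, and so was miR159a.1 (-2.38), although the latter was at 0.094, 0.79 and -0.38 with scaling to listed miRNA reads, TMM and DESeq2 and not counted there. miR168a, which targets an Argonaute gene, was lower at -1.86 but at 0.62, 1.31 and 0.14 with scaling to listed miRNA reads, TMM and DESeq2. miR444b.1 was at -0.14, not counted, but was higher at 2.34, 3.03 and 1.86 with scaling to listed miRNA reads, TMM and DESeq2, and miR319a, miR395b and miR397a had too few reads.

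The counts of this comparison depended on scaling: relative to the median of all miRNAs 12 were at least 2-fold higher and 17 at least 2-fold lower. With scaling to listed miRNA reads, TMM and DESeq2 the counts were 12 higher and 15 lower, 17 and 12, and 10 and 18, and the median moved by 2.48, 3.17 and 2.0. Besides those given, miR156a was not counted with scaling to listed miRNA reads (-0.98) or TMM (-0.28), nor with TMM were miR167a (-0.84), miR172a (-1.14) and miR827 (-1.08).

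**Figure D4:**
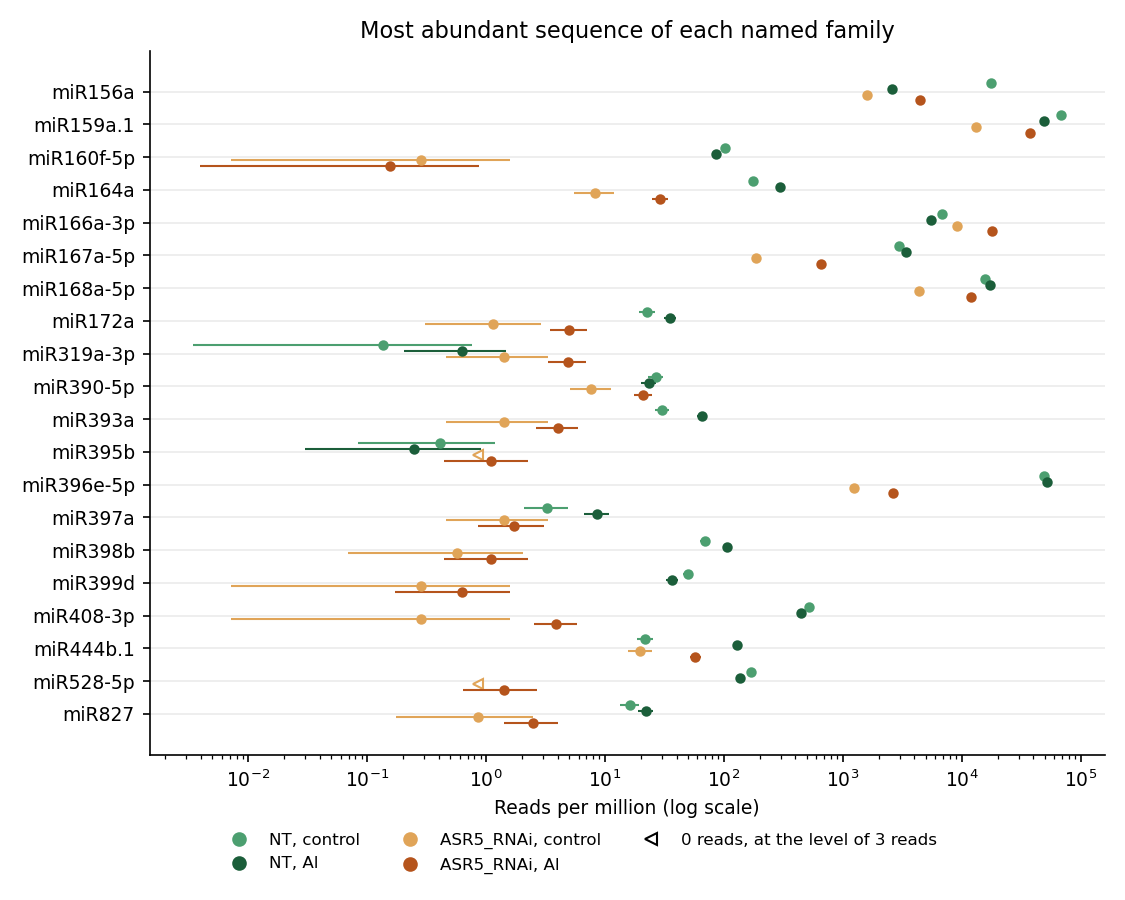
Levels in RPM, on a log axis, of the most abundant listed sequence of each of 20 families in the 4 libraries, with exact Poisson 95% intervals as bars and open triangles at the level of 3 reads where none was read. miR396e-5p went from 49136 RPM in NT control to 1234 RPM in ASR5_RNAi control, a decrease that is smaller with the other scalings.

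With Al, of 45 measured miRNAs 5 were higher in ASR5_RNAi than in NT and 25 were lower, with a median log2 ratio of -1.43. miR164e was 302.6-fold higher (log2 8.24, 7.26 to 9.46), a ratio that rests on 8 reads in NT Al, against 36 in NT control. miR164d (2.37), miR166a-3p (1.70), miR1850.1 (1.28) and miR164c (1.07, 0.21 to 1.97) were also higher. The largest decreases were in miR396c-5p (-10.13, -10.88 to -9.47), miR160f (-9.10, -14.40 to -6.62), which targets auxin response factors, and the copper miRNAs miR408-5p (-7.37), miR408-3p (-6.83), miR528-5p (-6.59) and miR398b (-6.59). In RPM, 8 miRNAs were at least 32-fold lower in ASR5_RNAi under both conditions: miR160f, miR166k-3p, miR396c-5p, miR398b, miR408-3p, miR408-5p, miR528-5p and miR399d. With TMM scaling 3 of the 8 were (miR160f, miR396c-5p and miR408-3p), and 5 with scaling to listed miRNA reads and with DESeq2.

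By group, 5 of 5 copper miRNAs were lower with Al in ASR5_RNAi than in NT, miR397a (-2.31, and -0.58 and not counted with TMM) among them, with a median of -6.59 at percentile 0 that was -4.87 with TMM scaling. Of 3 miRNAs against growth-regulating factors 2 were lower, with a median of -4.30 at percentile 3.57, which was that of miR396e-5p and was -2.58 with TMM scaling. With each of the 3 other scalings 1 of them was higher and 2 were lower. Of 11 auxin miRNAs 3 were higher and 5 lower (6 and 3 with TMM), among these miR393a (-4.00), miR164a (-3.35) and miR167a (-2.39, and -0.67 and not counted with TMM). The group median was -0.17 at percentile 99.38, but 0.66, 1.55 and 0.71 with scaling to listed miRNA reads, TMM and DESeq2, and miR390, at -0.17 and not counted, had the same ratios as the median. Of 5 HD-ZIP III regulators 1 was higher (3 with TMM and with DESeq2) and 2 were lower, namely miR166k-3p (-6.40) and miR166g-3p (-4.46), with a median of 0.13 at percentile 88.5 that was 0.95, 1.85 and 1.01 with scaling to listed miRNA reads, TMM and DESeq2. None of 3 SPL regulators was counted, but 2 were higher with each of the other scalings, with a median of 0.44 (2.16 with TMM scaling) at percentile 93.66 and miR156a at 0.78 (1.61, 2.50 and 1.66 with the other scalings). Of 6 monocot or rice miRNAs 1 was higher and 3 lower, and their median of -1.02, at percentile 78.88, was 0.71 with TMM scaling. With scaling to listed miRNA reads, TMM and DESeq2 1, 3 and 2 of them were higher and none was lower. miR399d (-5.88), miR827 (-3.14) and miR172a (-2.82) were lower, as was miR444b.1 (-1.17), which was at 0.56 with TMM scaling and not counted with scaling to listed miRNA reads (-0.34) or DESeq2 (-0.29). miR159a.1 (-0.37) and miR168a (-0.54) were not counted, but with scaling to listed miRNA reads, TMM and DESeq2 miR159a.1 was at 0.46, 1.35 and 0.51 and miR168a at 0.29, 1.19 and 0.35, both counted as higher with TMM, and miR319a and miR395b had too few reads.

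The median of the Al comparison of genotypes moved by 0.83, 1.72 and 0.88 with scaling to listed miRNA reads, TMM and DESeq2, with 11 higher and 19 lower, 19 and 14, and 14 and 18. Relative to the median, 17 were at least 2-fold higher and 15 at least 2-fold lower. Across the 42 miRNAs measured under both conditions, the ratios of ASR5_RNAi to NT had a Pearson r of 0.92 and a Spearman rho of 0.87, again across miRNAs. Of 31 and 24 lower miRNAs 22 were shared, where 17.7 would be shared by chance, and 34 of 42 lay on the same side of both medians. With 1 library per group, genotype could not be separated from any difference between library preparations.

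Fragments of tRNA also differed between genotypes. The median of 5 cytosolic tRNA fragments was 8.81-fold higher in ASR5_RNAi under control conditions and 2.29-fold higher with Al. Fragments of 9 chloroplast tRNAs with enough reads among 13 that had not been looked at when the comparison was set had a median log2 ratio of -3.35 in control and -4.98 with Al, or 10.2-fold and 31.6-fold lower in ASR5_RNAi. Among 7 chloroplast fragments already seen, the median was -3.36 and -5.32, but that of the histidine tRNA was 11.2-fold higher in ASR5_RNAi control. Summed over all listed chloroplast fragments, reads were 2.06-fold higher in ASR5_RNAi control (12738 against 6191 RPM) and 4.93-fold lower with Al. The histidine fragment carried the sum in control, with 10687.5 RPM in ASR5_RNAi and 953 RPM in NT. Without it, the other listed chloroplast fragments together were lower in ASR5_RNAi control than in NT control. The 5.8S rRNA fragment was 2.03-fold lower in control and 1.78-fold lower with Al. All these fragment ratios are in RPM. Scaling to listed miRNA reads, TMM and DESeq2 moves log2 ratios of the genotypes by 2.48, 3.17 and 2.0 in control. With Al it moves them by 0.83, 1.72 and 0.88. The 5.8S log2 ratio in control (-1.02) turns positive under each, and TMM takes up most of the chloroplast medians in control.

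**Figure D5:**
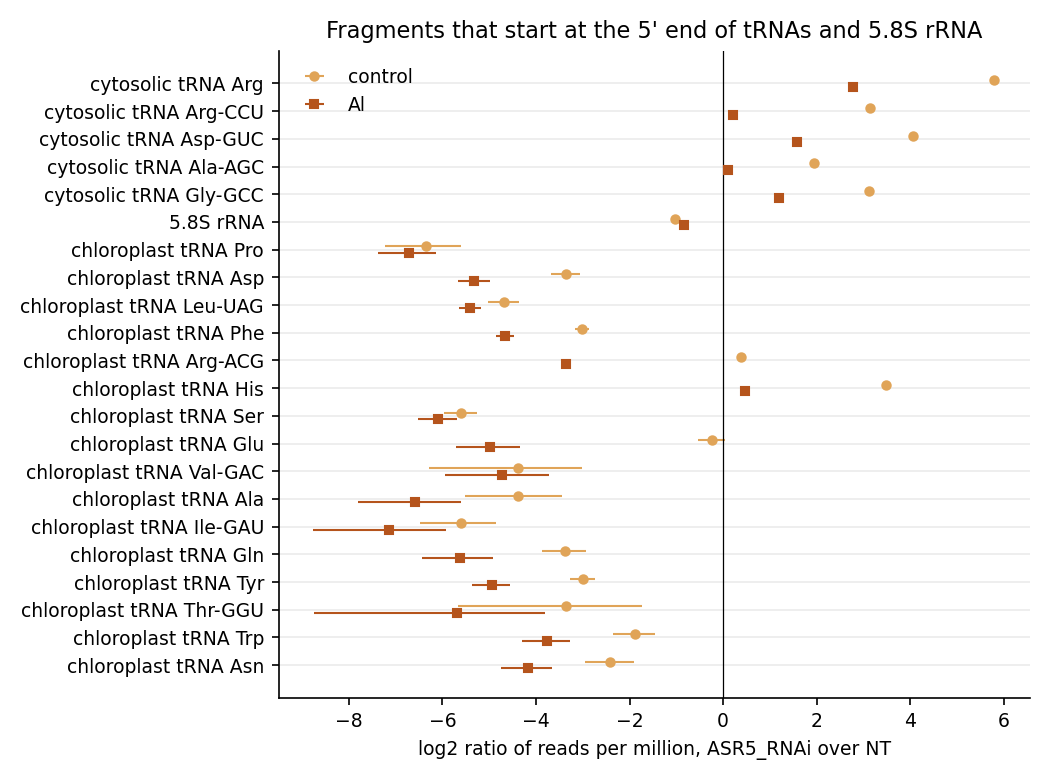
Log2 ratios of RPM, ASR5_RNAi over NT, of fragments from the start of cytosolic tRNAs, 5.8S rRNA and chloroplast tRNAs in control and in Al, with 95% counting intervals as bars. The 5 cytosolic tRNA fragments lay above 0 in control, and the chloroplast fragments lay below 0 except those of histidine (both conditions) and arginine (control).

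Beyond the list, 690 sequences reached 100 RPM in at least 1 library. Of these, 7 were at least 4-fold higher with Al in both genotypes and 1 was lower. Of the 7, 4 were 22 nt long, began with TC and ended with CCA, and 1 matched the joined silencing construct. In the comparison of genotypes, 431 were higher and 85 lower in ASR5_RNAi under both conditions. All these counts are in RPM alone, and they depend on the scale. The other scalings move log2 ratios of the genotypes by 2.0 to 3.17 in control and by 0.83 to 1.72 with Al. They move the Al ratios in ASR5_RNAi by -1.27 to -1.37. Of the 431, 174 (40.4%) matched the joined silencing construct. It was built from reads at least 50-fold higher in ASR5_RNAi, so this share was partly set by that choice.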

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

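The tests on miR156a in this part were chosen after the result was seen.

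miR156a differed between the genotypes in its response to Al: its log2 ratio was -2.77 in NT and 1.46 in ASR5_RNAi, opposite ways, with a difference of 4.23 that was not tested because each group had 1 library. The ratio in ASR5_RNAi was that of the common shift of its pair (median 1.45) and was 0.11, 0.096 and 0.19 with scaling to listed miRNA reads, TMM and DESeq2, so the size of the ratio in ASR5_RNAi and part of the difference rest on the scale. A shift from the 20 nt to the 21 nt form of miR156, TTGACAGAAGAGAGTGAGCAC, would raise the longer form, but that form was lower with Al in NT as well (log2 -2.80). Scaling of the NT libraries would move all miRNAs alike, but miR156a lay -2.89 from the median of the other listed miRNAs. A response of the NT plants to Al may remain, as a hypothesis found on the same data, and a difference between single plants or preparations stays open because there was 1 library per group.

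miR166e-3p also had opposite log2 ratios with Al, -1.34 in NT and 1.19 in ASR5_RNAi, a difference of 2.52 that was not tested and that carried the common shift of the ASR5_RNAi pair. Its ratio in ASR5_RNAi was -0.16, -0.18 and -0.082 with scaling to listed miRNA reads, TMM and DESeq2, so the opposite directions rest on the scale. That ratio also rests on 15 reads in ASR5_RNAi control and 62 in ASR5_RNAi Al. miR166e-3p differs from the abundant miR166a-3p in a single base. Its reads may be variants of miR166a-3p, which was not tested.

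Sequences of human miRNAs, listed as controls for foreign reads and used in no comparison, were above their level in the NT libraries: let-7a was at 17.03 RPM in ASR5_RNAi control and 11.4 in ASR5_RNAi Al, against 1.09 and 0.501 in NT control and Al. miR-21 was at 22.1 and 12.4 RPM in ASR5_RNAi control and Al, against 0.816 and 0.251 in NT. The 5 Arabidopsis sequences had 0 reads in each library.

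Reads of 22 nt that begin with TCG and end with CCA, which entered the comparisons only among the unlisted sequences and were not examined as a class, were at 4035 RPM in ASR5_RNAi Al, against 688 in ASR5_RNAi control, 770.4 in NT control and 874 in NT Al.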

How the results depend on the processing

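Scaling without reads of 18 and 19 nt and without tRNA and rRNA fragments, the joined ASR sequence, and the scalings of its ratios and of the miRNAs at least 32-fold lower, were chosen after the data were seen. The cause was not tested for any value below unless stated. No pairing of replicates was possible because each group had 1 library, numbered 1 throughout, and for the same reason no library could be left out. An additive model of genotype and Al was possible but was not fitted. Not run, because the reference held no sequences: scaling to genome matches, size classes of genome matches, and unique matches to ASR5.

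Among the ratios of single named miRNAs, counting as reversed a change of sign of a ratio called higher or lower, TMM kept 21 within their interval, moved 67 and reversed 5. DESeq2 scaling kept 26, moved 64 and reversed 3, scaling to listed miRNA reads kept 19, moved 70 and reversed 4, and isomiRs kept 73, moved 19 and reversed 1. Scaling without short reads and fragments kept 62 and moved 31. Among ratios that were not called, the sign changed in 8 with scaling to listed miRNA reads, 5 with TMM, 7 with DESeq2 and 1 without short reads and fragments.

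With Al in NT, 6 were higher (10 before) at a minimum of 500 reads, where fewer miRNAs enter, and lower counts (4 before) were 8 with isomiRs and 1 with summed families, which pool members. With Al in ASR5_RNAi, higher counts (24 before) were 2 with scaling to listed miRNA reads, 2 with TMM, 2 with DESeq2 and 13 at 500 reads, and lower counts (0 before) were 1 with listed miRNA reads and 1 with TMM. For ASR5_RNAi against NT in control, higher counts (2 before) were 12 with listed miRNA reads, 17 with TMM, 10 with DESeq2, 4 with no minimum, 0 at 500 reads and 0 with families. Lower counts (31 before) were 15, 12 and 18 with the 3 scalings and 19 at 500 reads. With Al, higher counts (5 before) were 11, 19 and 14 with the 3 scalings, 3 at 500 reads, 10 with isomiRs and 2 with families, and the lower count (25 before) was 14 with TMM. For the difference of the Al response, positive counts (17 before) were 2, 3 and 3 with the 3 scalings, 11 at 500 reads and 10 without short reads and fragments. Negative counts (1 before) were 7, 7 and 5 with the 3 scalings, 0 at 500 reads, 0 with families and 2 without short reads and fragments.

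With TMM scaling, which shifts all miRNAs of a comparison by 1 factor, group medians of the pairs that include an ASR5_RNAi library were as follows. HD-ZIP III regulators were at -0.36 with Al in ASR5_RNAi (1.01 before; 0.63 without short reads and fragments) and at 0.77 for ASR5_RNAi against NT in control (-2.40 before). SPL regulators were at -0.28 in control (-3.46 before; -2.21 with isomiRs) and 2.16 with Al (0.44 before). HD-ZIP III regulators were at 1.85 with Al (0.13 before). Auxin miRNAs were at 0.32 with Al in ASR5_RNAi (1.68 before) and 1.04 for genotypes in control (-2.13 before) and 1.55 with Al (-0.17 before). Copper miRNAs were at -4.10 in control (-7.28 before) and -4.87 with Al (-6.59 before), and growth-regulating factor miRNAs at -2.58 with Al (-4.30 before). Monocot or rice miRNAs were at 0.017 with Al in ASR5_RNAi (1.38 before), 2.54 for genotypes in control (-0.63 before) and 0.71 with Al (-1.02 before).

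Reversed single miRNAs among those called were miR1432-5p with Al in NT (-0.60 with isomiRs), miR396e-5p with Al in ASR5_RNAi (-0.25, -0.26 and -0.16 with listed miRNA reads, TMM and DESeq2), and, for genotypes in control, miR159a.1 (0.094 and 0.79 with listed miRNA reads and TMM), miR168a (0.62, 1.31 and 0.14 with the 3 scalings) and miR390 (0.67, 1.36 and 0.19). For genotypes with Al, miR444b.1 was at 0.56 with TMM. Of those not called, the sign changed with all 3 scalings for miR166a-3p with Al in ASR5_RNAi (-0.38, -0.40 and -0.30; 0.97 before) and miR444b.1 for genotypes in control (2.34, 3.03 and 1.86; -0.14 before). It also did for genotypes with Al in miR159a.1 (0.46, 1.35 and 0.51; -0.37 before), miR168a (0.29, 1.19 and 0.35, against -0.54 before) and miR390 (0.66, 1.55 and 0.71, against -0.17 before).

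Among distinct sequences in place of reads, 21 nt made up 6.13%, 6.59%, 7.81% and 7.71% and 24 nt 68.2%, 66.5%, 51.7% and 57.5% in NT control, NT Al, ASR5_RNAi control and ASR5_RNAi Al, so 24 nt was still lower in ASR5_RNAi. With reads of 18 to 24 nt the ASR part was at 12.9, 14.5, 29594 and 54359 RPM, and with antisense reads alone at 2.72, 2.51, 9812 and 17667 RPM. The log2 ratio of the ASR part with Al in ASR5_RNAi (0.90 before) was -0.45, -0.46 and -0.37 with the 3 scalings and 0.53 without short reads and fragments. For ASR5_RNAi against NT it was 13.64, 14.34, 13.17 and 11.69 in control (11.17 before) and 12.80, 13.70, 12.85 and 12.10 with Al (11.97 before). The 8 miRNAs at least 32-fold lower in ASR5_RNAi under both conditions were 5, 3 and 5 with the 3 scalings and 8 without short reads and fragments. Unlisted sequences at least 2-fold apart with Al in both genotypes numbered 91 higher and 10 lower. At 20 RPM they numbered 107 higher and 37 lower with Al, and 2691 higher and 355 lower in ASR5_RNAi, as a lower limit admits more sequences. Counts of unlisted sequences are in RPM alone. ASR5_RNAi control had 3522239 reads, the fewest, so a count of 0 there has an upper 95% limit of 1.05 RPM.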

Other observations

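All tests in this part were chosen after the result was seen, except that on 13 chloroplast tRNA fragments, which was set before their values were looked at. Its prediction came from 7 other chloroplast fragments already seen, and 9 of the 13 had enough reads.

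Forms outside the list also differed between the genotypes, and were chosen after their values were seen. The 5p arm of miR166, GGAATGTTGTCTGGTTCAAGG, was 38.1-fold higher in ASR5_RNAi than in NT under control conditions and 139-fold higher with Al, from 39.2 and 37.0 RPM in NT. The 22 nt form of miR167, TGAAGCTGCCAGCATGATCTGA, was 11.05-fold and 7.29-fold lower in ASR5_RNAi, and 1.73-fold higher with Al in NT, where it reached 51868 RPM. These forms belong to families that target HD-ZIP III genes and auxin response factors. Their ratios are in RPM, and TMM scaling moves log2 ratios of ASR5_RNAi to NT by 3.17 in control and 1.72 with Al. The miR167 form was at -3.47 and -2.87 in RPM, so most of its decrease in control rests on the scale.

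The 8 miRNAs at least 32-fold lower in ASR5_RNAi under both conditions in RPM form 1 pattern, although 3 of them were with TMM scaling, under which the smallest decrease among the 8 was 10.3-fold in control and 17.8-fold with Al. A uniform loss of miRNA reads was argued against by the spread of log2 ratios, whose interquartile range was 2.66 times that of the Al comparison in NT. Bias in capture set by the read ends was argued against for miR160f, whose same-end relative differed from it by 6.80 in log2 ratio. For miR166k-3p the difference was 9.30, but its relative, miR166m, differs from the abundant miR166a-3p only in its last base. Reads of miR166m (121 against 50353 of miR166a-3p in NT control) may be variants of miR166a-3p, which was not tested, so that pair cannot decide. This bias also stays open for the other 6, of which 0 had a measured same-end relative. Tissue with fewer chloroplasts in the ASR5_RNAi shoots could be neither supported nor excluded. Chloroplast tRNA fragments had a median log2 ratio of -3.35 or lower in both comparisons in RPM, but TMM scaling moves ratios in control by 3.17. The fragment of the histidine tRNA was 11.2-fold higher in control, and through it alone their sum was 2.06-fold higher. This explanation therefore stays open. An effect of ASR5 silencing on these miRNAs stays among the open explanations, as untested.

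A second pattern was the higher level of nearly all miRNAs with Al in ASR5_RNAi, with a median log2 ratio of 1.45. Short reads and tRNA fragments took a larger part of the ASR5_RNAi control library. Leaving short reads and the listed fragments out of the scaling brought the median to 1.07, so these might account for part of the higher level. Fragments outside the recalled list stayed in the scaling. The remaining shift therefore cannot decide whether short reads and fragments account for the whole. The 28 ratios had an interquartile range of 0.60. A shift of the scale, a response to Al and a difference in how the library was made stay open, as 1 library per group cannot separate them.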
